A study of Mus musculus with 12 samples.

How the data were processed

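N6-methyladenosine (m6A) was mapped by methylated RNA immunoprecipitation and sequencing (MeRIP-seq) in testes of mice at postnatal day 18. The libraries came from wild-type (WT) males and from males without Alkbh5 (KO). Per the labels' protocols, polyadenylated RNA was purified from total testis RNA, broken into fragments and pulled down with an antibody against m6A. The pulled-down fragments gave the IP libraries, and input libraries stand beside them. The libraries were paired-end and strand-marked with dUTP, per the labels' protocols. There were 12 libraries in 4 groups (WT IP, WT input, KO IP and KO input) of 3 replicates each. The groups and replicate numbers were read from the sample titles.

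The deposited data are 1 peak list per genotype, each comparing the IP libraries of that genotype with its input libraries. Per the submitters' processing notes, fastp, FastQC, HISAT2, HOMER and StringTie were used, without versions or roles, and the genome build was GRCm38. The peak caller is not given in the sources used here, nor whether the replicates of a genotype were pooled or called jointly. Each list gives, per the file headers, a fold enrichment for each peak, which is a linear ratio of IP over input made by the authors. Each list also gives, per the file headers, the log10 of the p-value and of the false discovery rate (FDR) of each peak, handled here as a score with no fixed range because the smallest values run off the scale. The span of each peak in bases, introns included, was deposited too, and is 1 base too long because starts are counted from 0. Fold, p and FDR are the authors' own values per peak, and they were used here to describe, rank or filter peaks within a list. Whether folds from 10 to 100 were whole multiples of 1 step per list was tested after seeing the data, counting a fold when the multiple rounded to the listed decimal. The step was the one with the most matches beyond chance. The highest p listed was 0.0501 in both lists, and the highest FDR was 0.406 in the WT list and 0.43 in the KO list.

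No values per library were used here, so the depth per sample is unknown and no replicate error could be computed. The planned tests of expression and of enrichment between genotypes, which needed values per library, were not run. Shares carry Wilson 95% intervals, and differences between 2 shares carry Newcombe 95% intervals. The coding difference among shared pairs is an exception and carries a paired Wald 95% interval. All of these cover counting error only, treat peaks or pairs as independent, and do not cover the spread between mice. No p-value was computed across peaks or genes.

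Peak positions are given from 1 in GRCm38. Peaks of the 2 lists were compared from start to end on the same strand with bedtools 2.31.1, since the lists carry no exon blocks. A peak was called shared when at least 1 base overlapped a peak of the other list, and otherwise WT-only or KO-only. Among WT peaks 9.22%, and among KO peaks 8.83%, shared bases with a peak of the same list on the opposite strand. For a description of chance overlap, KO peaks were moved at random within their gene spans, introns included, 100 times. Genes and position classes (5' UTR, coding exon, 3' UTR, noncoding exon, intron) were taken from the authors' annotation, which has no class for the stop codon.

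Before the data were examined, 20 gene lists with 476 genes in all, the overlap rule, the alternatives and the rule for named genes were fixed. For each list, the net share was the number of members with a KO-only peak minus the number with a WT-only peak, as a percentage of the members with a peak in either genotype. Its percentile was taken among 10000 random lists of the same size, drawn from all genes with a peak and matched on the number of merged peak positions per gene. Ties counted to equal parts on either side. A list is said to lean when it lay at or below the 2.5 or at or above the 97.5 percentile, which chance gives to 5% of lists. Terms of the Gene Ontology (GO) and of KEGG in the authors' annotation with 30 to 500 genes were handled alike, with tails of 0.5%. GO text was removed before use from 9.68% of WT and 10.1% of KO peaks, so term sizes are incomplete. Older symbols were matched through RefSeq gene names (GRCm38.p6), in which 16099 of the 17805 gene symbols with a peak were found.

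The genes named were Alkbh5, then from each list up to 4 members, namely the 2 with the highest fold in a KO-only peak and the 2 with the highest fold in a WT-only peak, filled up with shared peaks. To these were added, for each genotype, the 10 genes with the highest fold in a genotype-only peak and the 5 with the most genotype-only peaks, leaving out clone-type names. The 5 genes with the highest fold in a shared peak of the WT list, again without clone-type names (predicted genes, RIKEN clones and the like), completed the set. Some genes that this rule takes are not reported here. Members named at the stricter FDR were chosen after their values were seen.

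The list test was tested on simulated data in the table of 17805 genes. Of null lists, 5.4% fell beyond the tails. For these, the genotype-only calls at the authors' threshold were shuffled among genes with like numbers of merged peak positions. The random lists were matched in the same way, so a rate near 5% follows from the setup. It does not cover differences between genes in expression, on which the lists were not matched. A list of 35 members was found in 64% of 100 data sets when 25% of its members were set to KO-only, and in 100% when 50% were. All toy peaks with known overlaps were called correctly.

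The alternatives fixed beforehand were an FDR at or below 1e-05 (such peaks were searched for in the other list as deposited), a fold of at least 4, an overlap of 50% of the shorter peak or of 50% of both, and equal list lengths. Added after seeing the data were overlap on either strand, an FDR at or below 0.05, spans of at most 1000 bases, partners within 200 bases, random lists from protein-coding genes or from genes with a term, and the matching of genes by position. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Motifs and exon structure were not analysed here.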

Results

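Alkbh5 removes the methyl group of m6A, the most common internal modification of messenger RNA. The series asked how the m6A map of spermatocytes differs without it, using whole testes at postnatal day 18, when the most advanced germ cells of the initial wave are in or around meiosis. MeRIP-seq was made from 3 WT and 3 KO replicates, each with an IP and an input library, 12 libraries in all. The data analysed are the authors' peak lists, 1 per genotype. The depth of each library is unknown, and there is no replicate error. Differences below are therefore differences between the 2 lists, and their intervals cover counting error only.

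The targeted gene was examined before all others. Alkbh5 (ENSMUSG00000042650, chromosome 11, plus strand) had 3 peaks in the WT list and 0 in the KO list. The WT peaks lay in the 5' UTR (60536381 to 60538439, authors' fold enrichment 7.22), in a coding exon (60538649 to 60538858, fold 3.19) and in the 3' UTR (60557824 to 60558033, fold 3.77). The absence of Alkbh5 peaks goes with the KO label of the list. The deleted part of the gene is not given in the labels, and a peak list does not show the level of the transcript.

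Both genotypes carried m6A peaks on similar numbers of transcripts and at similar positions. The WT list held 33078 peaks in 16367 genes and the KO list 32277 peaks in 15723 genes. The median fold was 6.02 in the WT list and 6.32 in the KO list, and the median span was 361 and 390 bases. Many of the listed folds moved in steps, above all those of genotype-only peaks. Of genotype-only peaks with a fold from 10 to 100, 95.8% (94.1 to 97.0) in WT were whole multiples of 0.926 and 96.9% (94.7 to 98.2) in KO were whole multiples of 0.902, against 10.8% and 11.1% by chance. Among shared peaks these shares were 55.4% (54.2 to 56.5) and 52.7% (51.5 to 53.8), and over all peaks of such folds 59.0% and 55.0%. The input under these peaks is unknown, and a fold set by a floor of input is not an exact ratio. The 3' UTR held the largest share of peaks, 48.9% (95% interval 48.3 to 49.4) in WT and 48.8% (48.2 to 49.3) in KO. Coding exons held 17.8% (17.4 to 18.2) of WT and 19.5% (19.0 to 19.9) of KO peaks, and noncoding exons 16.6% (16.2 to 17.0) and 14.7% (14.3 to 15.1). An FDR above 0.05 was listed for 14.7% of WT and 15.1% of KO peaks. With the FDR limited to 1e-05 or below, called the stricter FDR from here on, the lists held 16973 WT and 16833 KO peaks.

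Most peaks were shared between the genotypes. Of the WT peaks 25939, or 78.4% (78.0 to 78.9), overlapped a KO peak, and of the KO peaks 26037, or 80.7% (80.2 to 81.1), overlapped a WT peak. KO peaks moved at random within their genes overlapped on average 23.7% of WT peaks (range 23.3 to 24.1 over 100 shuffles). These moves took in introns, to which only 4.07% of WT and 3.97% of KO peaks were annotated. The shuffled share therefore understates the chance overlap of peaks placed in exons alone. Outside clone-type names, the strongest shared peaks of the WT list lay in the 3' UTR of Dhx9, an RNA helicase (chromosome 1, 153455758 to 153457612), with a fold of 1350 in the WT and 1090 in the KO list, and in Rrbp1, Fam98b, Fbxl19 and Ube2s, with WT folds from 978 to 579. Genotype-only peaks numbered 7139 in WT (21.6%, 21.1 to 22.0) and 6240 in KO (19.3%, 18.9 to 19.8). They were shorter, with a median span of 176 bases in WT and 181 in KO, against 451 and 452 for shared peaks.

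The share of peaks without a partner fell with the FDR. In the WT list 58.2% (56.8 to 59.5) of peaks with an FDR above 0.05 had no partner, against 31.5% (30.7 to 32.4) between 0.05 and 1e-05, 8.30% (7.69 to 8.95) between 1e-05 and 1e-20 and 1.60% (1.37 to 1.87) at or below 1e-20. The KO list gave 56.0% (54.6 to 57.3), 27.5% (26.7 to 28.4), 7.31% (6.72 to 7.94) and 0.941% (0.769 to 1.15). By number, most partnerless peaks lay between 0.05 and 1e-05 (3539 WT and 2905 KO) or above 0.05 (2837 and 2734). The stricter FDR left 763 WT-only peaks in 689 genes and 601 KO-only peaks in 560 genes. Of the genes named by the rule, 13 of 65 with a WT-only peak and 17 of 66 with a KO-only peak had such peaks with an FDR above 0.05 alone. On the WT side these were Mettl16, Rbm15, Rbm15b, Hfm1, Dmc1, Chek1, Rarg, Cnot3, Hnrnpk, Tra2b, Fam184a, Ttn and Ube2s. On the KO side they were Alkbh2, Alkbh6, Igf2bp3, Mus81, Cpeb2, Piwil4, Morc1, Pnldc1, Ret, Spem1, Tnp1, Inhba, Ehmt1, Btg4, Srsf5, Mycbpap and Trim66. When 50% of both peaks had to overlap, 14570 WT-only and 13760 KO-only peaks were counted.

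**Figure D1:**
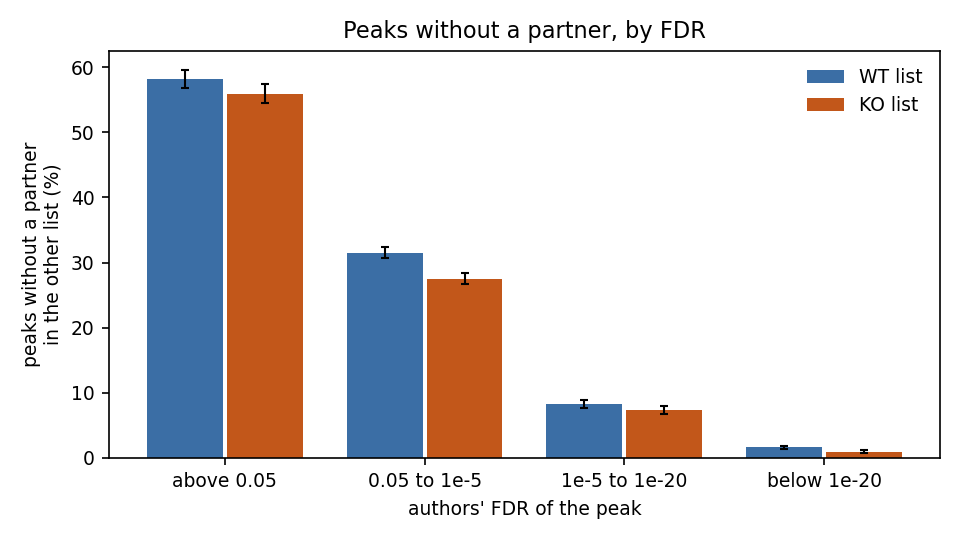
Share of peaks (%, vertical axis) with no overlapping peak in the other list, by the authors' FDR (horizontal axis), for the WT and the KO list; error bars are Wilson 95% intervals that cover counting error. The share falls from 58.2% in the WT and 56.0% in the KO list above an FDR of 0.05 through 31.5% and 27.5% between 0.05 and 1e-05 to 1.60% and 0.941% at or below 1e-20.

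At the level of genes, 14285 of the 17805 genes with a peak had peaks in both lists. The WT list alone named 2082 genes and the KO list alone 1438. Among the latter was Terb1, which attaches meiotic telomeres to the nuclear envelope, with 3 KO-only peaks and no WT peak. Its peaks lay on chromosome 8 in a coding exon (104472971 to 104473031, fold 2.53) and in the 3' UTR (104447810 to 104447990, fold 2.56, and 104447049 to 104447109, fold 4.06). Only the coding peak passed the stricter FDR (log10 FDR -10.3). The peak of fold 4.06 had an FDR above 0.05 (log10 FDR -0.707). Spag17 and Spag16, proteins of the axoneme, each had 2 WT-only peaks and no KO peak. With both lists limited to the stricter FDR, 1151 genes were in the WT list alone and 832 in the KO list alone.

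**Figure D2:**
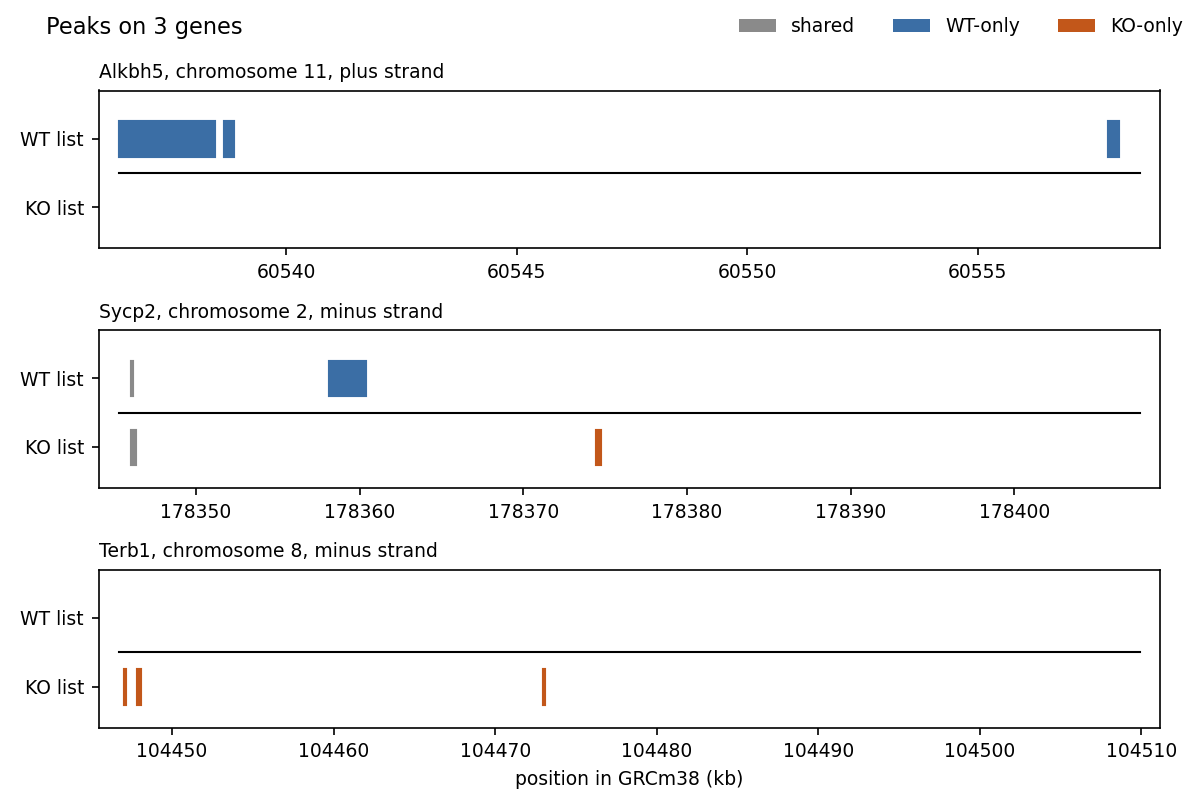
Peaks of Alkbh5, Sycp2 and Terb1 in GRCm38 (horizontal axis, kb), with WT peaks above and KO peaks below the line that marks the gene's extent; boxes are to scale apart from their outline. Alkbh5 has 3 WT peaks and 0 KO peaks, Terb1 has 3 KO peaks and 0 WT peaks, and Sycp2 has 1 shared, 1 WT-only and 1 KO-only peak.

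KO-only peaks lay in coding exons more often than WT-only peaks. Coding exons held 21.7% (20.7 to 22.7) of KO-only and 12.4% (11.7 to 13.2) of WT-only peaks, a difference of 9.27 percentage points (8.00 to 10.6). Shared peaks stood at 19.2% in the WT list. Noncoding exons showed the opposite, with 17.5% (16.6 to 18.5) of KO-only and 27.3% (26.3 to 28.4) of WT-only peaks, a difference of -9.77 points (-11.2 to -8.36). The 3' UTR held 36.6% (35.4 to 37.8) of KO-only and 38.3% (37.2 to 39.4) of WT-only peaks, and the 5' UTR 16.2% (15.3 to 17.1) and 13.9% (13.1 to 14.7). Under the stricter FDR coding exons held 36.6% (32.9 to 40.5) of KO-only and 10.6% (8.62 to 13.0) of WT-only peaks, a difference of 26.0 points (21.5 to 30.4). The noncoding difference was then -20.9 points (-24.6 to -17.2). In genes that also carry a shared peak, noncoding exons held 11.0% of KO-only and 14.0% of WT-only peaks, a smaller difference of -2.97 points (-4.39 to -1.55), and -6.92 points (-10.9 to -3.18) under the stricter FDR. The coding difference in those genes was 10.2 points (8.47 to 11.9). With 50% of both peaks required to overlap, the differences were 4.04 and -4.11 points.

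**Figure D3:**
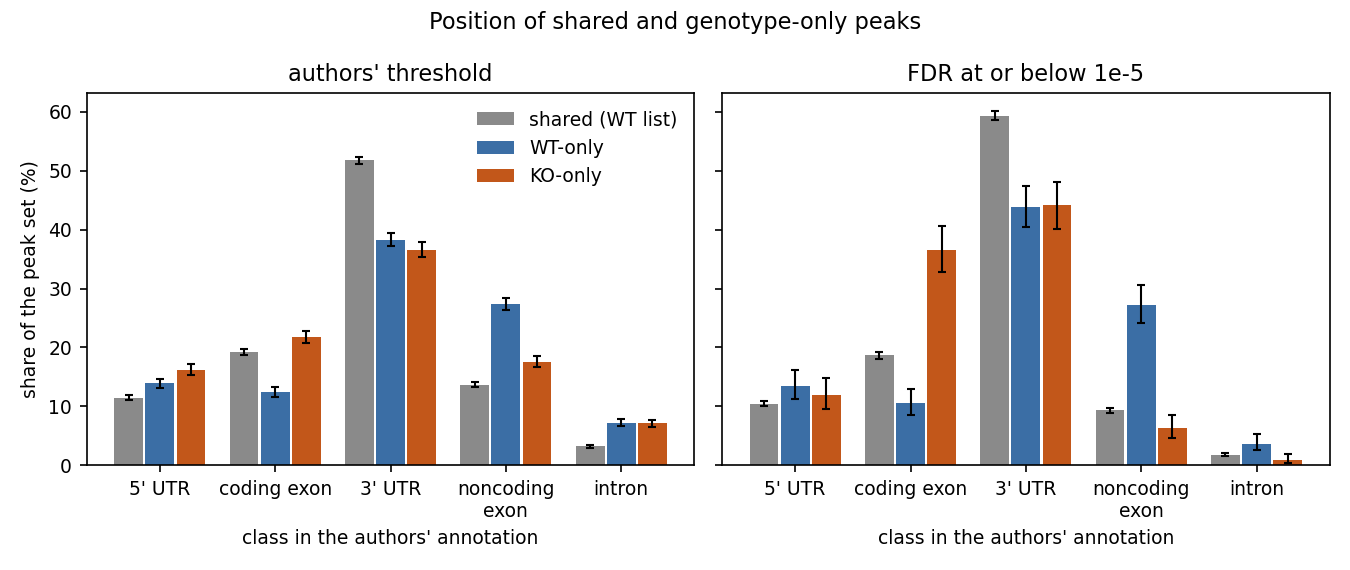
Share of shared (WT list), WT-only and KO-only peaks (%, vertical axis) in 5 classes of the authors' annotation, at the authors' threshold (left) and at an FDR at or below 1e-05 (right); error bars are Wilson 95% intervals that cover counting error. Coding exons hold 21.7% of KO-only and 12.4% of WT-only peaks on the left, and 36.6% and 10.6% on the right.

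Genes of the sperm tail carried WT-only peaks more often than KO-only peaks. Of the 22 members of the cilium and flagellum list with a peak, 16 had a WT-only and 6 a KO-only peak, a net share of -45.5% (percentile 0.215 of random lists). Spag17 had a WT-only peak of fold 15.7 in an intron (chromosome 3, 100008474 to 100008674) and Spag16 1 of fold 12 in an intron (chromosome 1, 70280818 to 70281117). The KO-only peaks of this list with the highest fold lay in an intron of Ccdc39 (fold 9.92) and a coding exon of Cfap44 (fold 7.22). Under the stricter FDR, 8 members (Ccdc39, Cfap65, Cfap69, Dnah17, Dnaic1, Ift140, Qrich2 and Spag17) had a WT-only peak and 1 (Dnah17) a KO-only peak (percentile 0, no random list as low). Dnah17, a dynein heavy chain of the outer arm, had both kinds, a WT-only peak in the 3' UTR (chromosome 11, 118023042 to 118023252, fold 5.08) and a KO-only peak in coding exons (118023371 to 118024707, fold 3.47).

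Other late germ cell genes leaned the same way at the stricter FDR. Of 26 round spermatid and spermiogenesis genes with a peak, 11 had a WT-only and 8 a KO-only peak at the authors' threshold (percentile 28.3). Under the stricter FDR these were 4 and 0 (percentile 0.65), namely Spz1, Catsper2, Spata16 and Ldhc. The peaks of Spz1 (log10 FDR -5.06) and Catsper2 (-5.29) passed that limit narrowly, and that of Spata16 (-94.4) clearly. The Ldhc peak had a fold of 1.17, near the lowest of the WT list (1.12). The 3' UTR peak of Spz1, a bHLH-zip transcription factor of testis, had a fold of 13.0 (chromosome 13, 92574636 to 92574872). Tssk6, a sperm kinase, had a WT-only 3' UTR peak of fold 12. KO-only peaks were listed in Spem1 (fold 8.12) and in Tnp1, a transition protein (fold 7.22).

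Genes of meiotic recombination carried KO-only peaks more often at the stricter FDR, but not at the authors' threshold. Of 35 meiotic recombination genes with a peak, 8 had a KO-only and 9 a WT-only peak (percentile 53.4). Of these genes, 6 (Brca2, Msh4, Msh5, Prdm9, Psmc3ip and Zcwpw1) had a KO-only and 2 (Brca2 and Tex15) a WT-only peak at the stricter FDR (percentile 99.4). Brca2, which loads recombinases at DNA breaks, had a KO-only peak across coding exons (chromosome 5, 150552944 to 150553981, fold 4.20). Its other KO-only peak (150539644 to 150539703, fold 2.86) ended just before the start of a WT-only peak (150539733 to 150540003, fold 2.85), and 9 further Brca2 peaks were shared. Among genotype-only peaks of this list at the authors' threshold, the highest KO-only fold lay in an intron of Mus81 (7.22), before the Brca2 peak of 4.20. The highest WT-only folds lay in the 5' UTR of Hfm1 (7.41) and the 3' UTR of Dmc1 (4.01).

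The pachytene transcription and cell cycle list had 7 members with a KO-only and 4 with a WT-only peak among 21 (percentile 90.5). The stricter FDR left 4 (Kctd19, Cdk1, Hspa2 and Aurka) and 0 (percentile 99.97). Kctd19, needed for male meiosis, had a KO-only coding peak (chromosome 8, 105386874 to 105387203, fold 4.54, log10 FDR -53.2) and no other peak in either list. Cpeb2 and Tcfl5 had peaks of both kinds, and Eif4g3 had shared peaks alone. The synaptonemal complex and axis list had 3 members with a KO-only and 5 with a WT-only peak among 12 (percentile 28.4). In it, Sycp2 had a KO-only coding peak (chromosome 2, 178374423 to 178374663, fold 3.61) and a WT-only coding peak (178358127 to 178360333, fold 1.37). Smc1a had 2 KO-only coding peaks, while Sycp3 (fold 3.26) and Rec8 (fold 2.12) each had a WT-only 3' UTR peak.

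The remaining meiotic and germ line lists lay inside the range of random lists. In the telomere attachment list 1 member of 9 had a KO-only peak (Terb1) and 1 a WT-only peak (Cdk2) (percentile 58.7), while Lmnb1 and Ccdc155 had shared peaks. In the DNA damage and sex body list 4 of 17 had a KO-only and 9 a WT-only peak (percentile 6.41). There, Atm had a KO-only coding peak of fold 13.5 and Atr 2 KO-only coding peaks, while Chek1 (fold 6.48) and Rnf8 (fold 3.52) had WT-only peaks. Among 16 meiotic entry regulators 2 had a KO-only peak (E2f6 and Gm4969, also known as Meiosin) and 5 a WT-only peak, Tet1 and Rarg among them (percentile 18.6). Of 21 piRNA pathway genes 6 had a KO-only and 7 a WT-only peak (percentile 49.0). Tdrkh, a Tudor protein of piRNA processing, had a WT-only 3' UTR peak of fold 29.6 (chromosome 3, 94426214 to 94426334). A shared KO peak of Tdrkh, also in the 3' UTR (94425885 to 94426154, fold 2.17), ended just before the start of this WT-only peak. Each list held 3 shared Tdrkh peaks. Pnldc1 had peaks of both kinds, and Piwil4 (fold 8.12) and Morc1 (fold 4.06) had KO-only peaks.

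**Figure D4:**
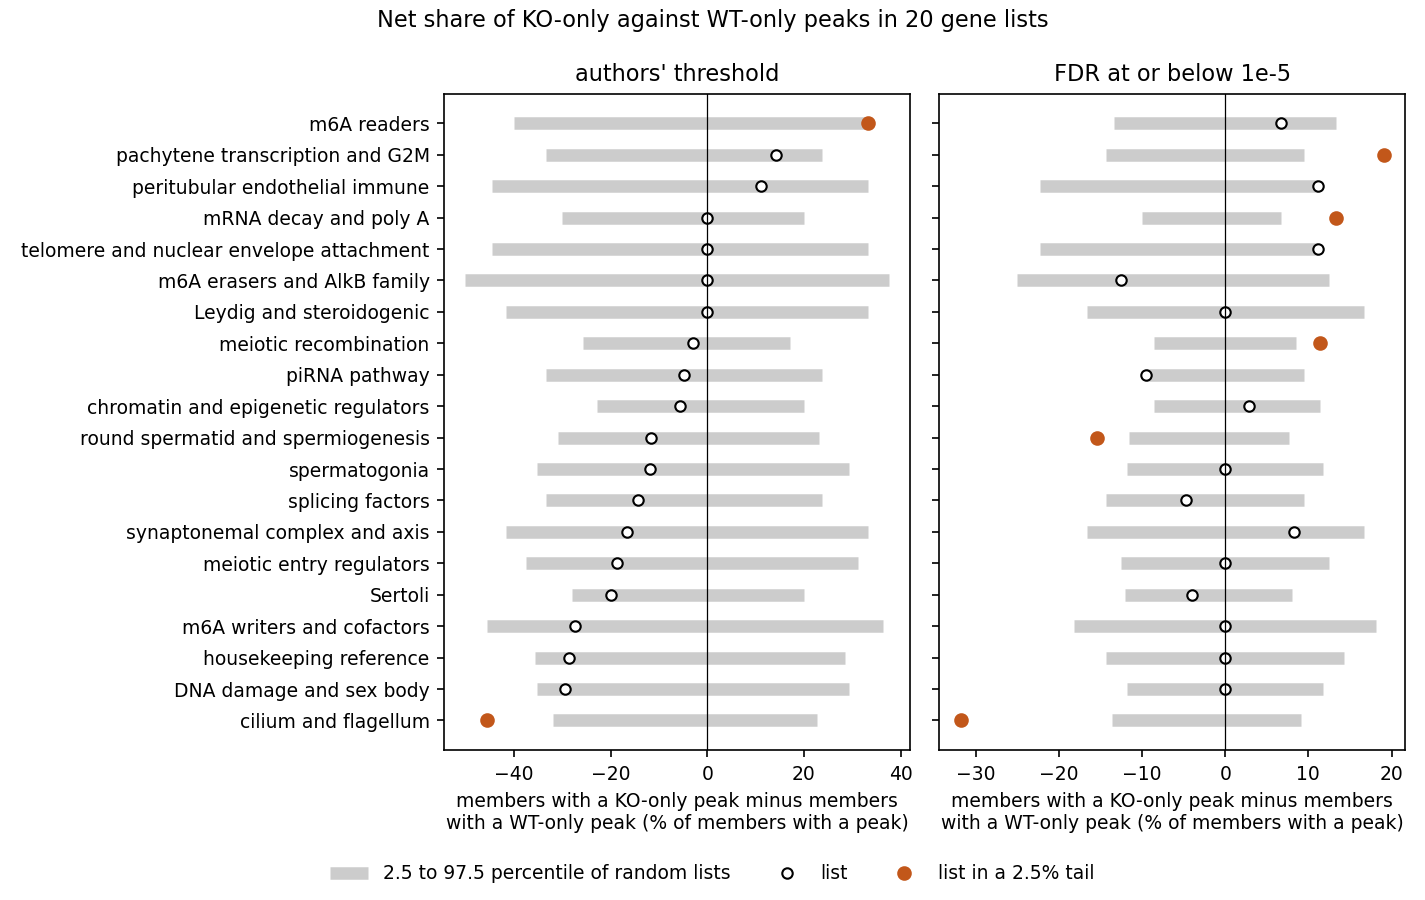
Net share of the 20 gene lists (horizontal axis, members with a KO-only peak minus members with a WT-only peak, % of members with a peak) at the authors' threshold (left) and at an FDR at or below 1e-05 (right); grey bars span the 2.5 to 97.5 percentile of 10000 random lists and filled points lie in a tail of 2.5%. The cilium and flagellum list lies at -45.5% on the left and -31.8% on the right, below the grey bar in both.

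Among proteins that bind, write or erase m6A, the reader list leaned to KO-only peaks. Of 15 readers with a peak 9 had a KO-only and 4 a WT-only peak, a net share of 33.3% (percentile 98.0). Prrc2a (3' UTR, fold 10.8) and Elavl1 (5' UTR, fold 9.02) had KO-only peaks, Fxr2 had a WT-only peak, and Igf2bp3 had peaks of both kinds. This lean was lost at equal list lengths (percentile 97.0), with 50% of both peaks required to overlap (85.9), with partners allowed within 200 bases (83.2) and at the stricter FDR (83.4), where Ythdc1 alone had a genotype-only peak. Of 11 writers and cofactors 2 had a KO-only and 5 a WT-only peak (percentile 13.5), with both kinds in Mettl14 and Mettl16, and WT-only peaks in Rbm15 and Rbm15b. Of 8 erasers and AlkB family members 2 (Alkbh2 and Alkbh6) had a KO-only and 2 (Alkbh5 and Alkbh8) a WT-only peak (percentile 59.1).

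Markers of spermatogonia and of somatic cells of the testis did not lean. In spermatogonia 2 of 17 marker genes had a KO-only peak (Ret and Gfra1) and 4 a WT-only peak, Uchl1 and Ccnd2 among them (percentile 34.2). Of 25 Sertoli cell genes 4 had a KO-only and 9 a WT-only peak (percentile 11.3), with KO-only peaks in Inhba and Cdh2 and a WT-only peak in Sox9. Of 12 Leydig cell and steroid synthesis genes 2 (Star and Lhcgr) had a KO-only and 2 (Insl3 and Hsd3b6) a WT-only peak (percentile 58.7). Of 9 peritubular, endothelial and immune genes 2 (Vwf and Cdh5) had a KO-only and 1 (Tagln) a WT-only peak (percentile 76.7), and Kdr had a shared peak. The percentiles of these 4 lists at the stricter FDR, in the same order, were 56.6, 25.8, 52.8 and 93.0. Genes with a KO-only and with a WT-only peak then numbered 0 and 0, 1 and 2, 2 and 2, and 2 and 1. Counts this small show neither a lean nor its absence.

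Among general regulators, mRNA decay genes leaned to KO-only peaks at the stricter FDR. Of 30 mRNA decay and poly(A) genes 6 had a KO-only and 6 a WT-only peak at the authors' threshold (percentile 64.1). With the stricter FDR, 4 (Pan2, Cnot7, Cnot6l and Pabpc1) had a KO-only peak and 0 a WT-only peak (percentile 99.8). At the authors' threshold the KO-only peaks of highest fold lay in Cpsf6 (12.6) and Btg4 (4.06), and the WT-only ones in Cnot3 (8.33) and Patl1 (7.41). Of 35 chromatin regulators 10 had a KO-only and 12 a WT-only peak (percentile 37.0), with a KO-only peak in Uhrf2, WT-only peaks in Brd2 and Tet2, and both kinds in Ehmt1. Of 21 splicing factors 4 had a KO-only and 7 a WT-only peak (percentile 25.7), Srsf5 and Bud31 on the KO side and Hnrnpk and Tra2b on the WT side. Of 14 housekeeping genes 3 had a KO-only and 7 a WT-only peak (percentile 9.29), with Rpl13a on the KO side, Gapdh on the WT side and both kinds in Tbp. In all, 2 of the 20 lists leaned at the authors' threshold and 5 at the stricter FDR, where chance gives 5% of lists. At the stricter FDR noncoding exons held 27.3% of WT-only and 6.32% of KO-only peaks. Random lists from protein-coding genes were run at the authors' threshold only. The leans to KO-only peaks at the stricter FDR were therefore not checked against such lists.

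Among genes without clone-type names, the WT-only peak of highest listed fold lay in the 3' UTR of Ube2v1, a ubiquitin-conjugating enzyme variant (chromosome 2, 167607668 to 167608056, fold 104). Listed next among these genes were Erich6 (5' UTR, 39.8), Entpd4b (34.3), Mag (34.3), Mycbpap (32.4), Pfn1 (31.5), Fem1al (30.6), Tdrkh (29.6), Mbd3l1 (28.7) and Abcg8 (25.0). The KO-only peak of highest listed fold in such genes lay in the 5' UTR of Pgam1, a glycolytic mutase (chromosome 19, 41911923 to 41912041, fold 46.9). After it came Pabpc1l2a-ps (28.9), Naa30 (24.4), Fam184a (24.4), Agap1 (23.5), Rnf128 (22.6), Sptbn5 (22.6), Hoxd13 (21.7), Anks1b (21.7) and Cilp (21.7). All 9 of these WT-only folds below 100 and all 10 of the KO-only folds were whole multiples of their list's step. Whether their order is one of exact ratios therefore cannot be told. Fsip2, a protein of the fibrous sheath of the sperm tail, Nsun4 and Trim66 had 6 WT-only peaks each, and Cngb1 had 5. Ttn had the most KO-only peaks of genes without clone-type names (10), followed by Chrnb2 (7) and by Adgrv1, Bptf and Dnhd1 (6 each). Of these genes, Cngb1 had no KO-only and Bptf no WT-only peak, and the other genes had both kinds.

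Among GO terms in the authors' annotation, cilium terms leaned to WT-only peaks and DNA repair to KO-only peaks at the stricter FDR. Of 617 terms, 8 leaned to WT-only and 21 to KO-only peaks there, where 3.08 are expected each way by chance. With random lists drawn from genes with a term, these were 8 and 13. Motile cilium had 17 genes with a WT-only and 1 with a KO-only peak among 92 (percentile 0), and cilium movement 9 and 1 among 32. Protein folding had 9 and 1 among 68 (percentile 0.055). DNA repair had 25 genes with a KO-only and 7 with a WT-only peak among 253 (percentile 100), microtubule organizing center 25 and 9 among 231, and chromatin binding 19 and 3 among 263. At the authors' threshold DNA repair did not lean (79 and 74, percentile 89.9), nor did chromatin binding (85 and 80, percentile 89.8), while motile cilium had 45 genes with a WT-only and 28 with a KO-only peak (percentile 2.43). Double-strand break repair had 8 genes with a KO-only and 17 with a WT-only peak among 40 there (percentile 4.205), and 4 and 1 at the stricter FDR (95.2). In all, 0 terms leaned to WT-only and 21 to KO-only peaks at the authors' threshold. Among these were microtubule organizing center (92 and 64), calcium channel activity (22 genes with a KO-only and 7 with a WT-only peak among 38), animal organ morphogenesis (20 and 5 among 47) and cell adhesion (126 and 92 among 305). The calls of these last 3 terms were lost at the stricter FDR, with 1 and 0 genes (percentile 82.1), 3 and 2 (76.8), and 9 and 3 (93.3). At the authors' threshold, random lists from genes with a term gave 3 WT-only and 14 KO-only terms. These WT-only terms were defense response to virus (38 WT-only and 21 KO-only genes), P-body (24 and 10) and cytoplasmic ribonucleoprotein granule (21 and 8). Of 216 KEGG terms at the authors' threshold, 0 leaned to WT-only and 1 to KO-only peaks. Terms share genes, so they are not independent of each other.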

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

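Overlap on either strand, an FDR at or below 0.05, spans of at most 1000 bases, partners within 200 bases, random lists from protein-coding genes or genes with a term, and genes matched by position were chosen after seeing the data. No paired analysis was possible because each genotype has 1 peak list and no values per library were used; the alternatives planned for expression (pseudocount, filter on low values, each replicate left out, replicate block) were not run. Overlap from start to end, planned as an alternative to exon blocks, is the main setting. The cilium and flagellum list leaned to WT-only peaks in all 6 alternatives run for it (percentiles 0 to 2.08), and coding exons were more frequent among KO-only than WT-only peaks in all 9 run for position (4.04 to 26.0 points). The 14 lists not named next stayed inside the range of random lists in each of the 6.

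At an FDR at or below 1e-05, by construction fewer peaks were left: 16973 WT and 16833 KO peaks (main 33078 and 32277), 763 WT-only and 601 KO-only (main 7139 and 6240), 16210 and 16232 shared (main 25939 and 26037), and 1151 genes in the WT and 832 in the KO list alone (main 2082 and 1438). The coding and noncoding differences were 26.0 and -20.9 points, and 2 lists leaned to WT-only (main 1) and 3 to KO-only peaks (main 1). Percentiles were 99.4 for meiotic recombination, 99.97 for the pachytene list, 99.8 for mRNA decay, 0.65 for round spermatids and 83.4 for m6A readers, and 8 GO terms leaned to WT-only peaks (main 0). A fold of at least 4 left 22044 WT peaks and 16451 WT and 16655 KO shared peaks, with a noncoding difference of -8.24. When 50% of both peaks had to overlap, 14570 WT-only and 13760 KO-only peaks were counted, with differences of 4.04 and -4.11, readers at 85.9 and 0 lists leaning to KO-only peaks. With 50% of the shorter peak the noncoding difference was -8.31. At an FDR at or below 0.05 there were 4302 WT-only and 3506 KO-only peaks, with differences of 12.9 and -13.3. Partners within 200 bases gave a noncoding difference of -11.2, readers at 83.2 and 0 lists leaning to KO-only peaks. Equal list lengths put the readers at 97.0, with 0 lists leaning to KO-only peaks. With random lists from genes with a term 3 GO terms leaned to WT-only peaks. Apart from the smaller numbers of peaks, the cause of these shifts was not tested.

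Of the named genes, 23 of 65 with a WT-only peak and 24 of 66 with a KO-only peak had one left at an FDR at or below 1e-05, and 61 and 57 with partners within 200 bases. Unknown depth limits all counts: a missing peak can be a missed one.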

Other observations

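The tests of shared-peak annotation, of the strength of partnerless peaks and of the round spermatid list were chosen after their results had been seen, as were the comparisons in the next paragraph, the flagellum set widened by a GO term and the setting with partners within 200 bases.

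Flagellum genes also differed among shared peaks. Taking the fixed cilium and flagellum list together with the GO term motile cilium, 102 genes had a peak. They held 79 shared WT peaks with an FDR at or below 1e-05, and for 20.3% (12.9 to 30.4) of these every KO partner had an FDR above 1e-05. Of 64 such KO peaks, 3.12% (0.861 to 10.7) had WT partners above 1e-05 alone. Over all genes these shares were 8.88% and 9.31%, and in DNA repair genes 4.56% and 6.48%. The FDR of a peak depends on transcript abundance and depth, so these shares do not measure methylation alone. WT-only peaks at an FDR at or below 1e-05 lay in genes with no KO peak in 45.8% of cases (42.3 to 49.3), while KO-only peaks lay in genes with no WT peak in 23.8% (20.6 to 27.4). The X chromosome, which is silenced in pachytene spermatocytes, did not stand apart. Its WT-only share was 20.5% (18.1 to 23.2) of 989 peaks and its KO-only share 21.3% (18.9 to 24.0) of 979.

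KO-only peaks lay in coding exons more often than WT-only peaks. Weak calls do not account for it, since the difference among peaks at an FDR at or below 1e-05 was 26.0 points (21.5 to 30.4), nor do shifted peak boundaries, since with partners allowed within 200 bases it was 9.94 points (8.58 to 11.3). Of 19371 shared pairs 2.95% were annotated to different classes, but the net KO minus WT coding share among them was -0.0103 points (-0.235 to 0.214), and in genes that also carry a shared peak the difference was 10.2 points (8.47 to 11.9), which argues against transcripts found in 1 genotype only. A shared peak in the gene does not exclude a transcript that differs in level, and expression was not analysed here. Differences between the genotypes' libraries in depth, fragment size or antibody efficiency stay open, since no values per library were used. A change of methylation in coding exons without the demethylase is a candidate explanation that these lists could neither exclude nor test.

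Peaks without a partner made up 21.6% of the WT and 19.3% of the KO list. Of those in both lists, 89.8% (89.3 to 90.3) had an FDR above 1e-05, against 37.6% of shared peaks and 48.3% of all peaks, so many may be weaker sites listed in 1 genotype by chance of detection. Calls close to the p threshold were fewer, as 41.6% (40.8 to 42.5) of the partnerless peaks had an FDR above 0.05, against 8.07% of shared peaks. Genes with no peak in the other list held 31.1% (30.3 to 31.9) of all partnerless peaks, which argues against transcripts found in 1 genotype only as the main source. At an FDR at or below 1e-05 this share was 45.8% for WT-only and 23.8% for KO-only peaks, so the argument is weaker for strong WT-only peaks. A gene without a peak can still be expressed. How many of the other partnerless peaks changed in methylation, or lay in transcripts that differ in level, was not tested.

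Flagellum genes at an FDR at or below 1e-05 were WT-only more often than KO-only. Of the 21 genes of the widened set with such a WT-only peak, 61.9% (40.9 to 79.2) had no KO peak at all, and of the 8 in the fixed list 37.5% (13.7 to 69.4). These intervals are wide. Transcripts absent from the KO also cannot be told apart from lost peaks, since a gene that lost its only peak has no KO peak either. Fewer late germ cells in the KO may contribute. The round spermatid list lay at percentile 0.65, and at 1.585 without its 4 members in the widened flagellum set (Akap3, Ldhc, Odf2 and Tssk1). The latter value rests on 3 genes with a WT-only peak (Spz1, Catsper2 and Spata16) and 0 with a KO-only peak. The peaks of Spz1 and Catsper2 lay close to the FDR limit. The widened set holds Catsperz but not Catsper2, so the removal of sperm tail genes may be incomplete. At the authors' threshold the round spermatid list lay at 28.3, inside the range of random lists. The pachytene list leaned to KO-only peaks at an FDR at or below 1e-05, with 4 genes that had a KO-only and 0 a WT-only peak (percentile 99.97). This lean does not count against fewer later germ cells, and the shares of cell types were not measured. The lists do not settle whether late germ cells were fewer. A difference in methylation of the flagellum transcripts stays open too, as expression was not analysed here.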
